A study of Homo sapiens with 36 samples.

How the data were processed

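RNA was sequenced from 36 libraries of IMR90 ER:RAS cells, which are human fibroblasts, with 12 groups of 3. Per the labels, cells of passage 14 were grown in 10% FBS for 6 days with a medium change on day 3, with or without 100 nM 4OHT, and then treated for 16 h or 36 h, in part with a caspase inhibitor. The labels give no dose for digoxin, ouabain or the inhibitor, and no drug was given to proliferating cells. RNA was extracted with TRIzol and RNeasy columns and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, reads were aligned to hg19 with TopHat2 2.0.11 and the deposited values are raw counts per gene from featureCounts. The version of featureCounts, its strand setting and the annotation release are not given in the sources used here. The values were whole counts for 57232 Ensembl genes, of which 10690 had no count in any library. Of the gene identifiers, 51058 came with a symbol, 309 more were named from GENCODE, 5865 stayed without a name and 935 share a symbol with another identifier. GENCODE was used for names, types, lengths and GC content only. Library totals lay between 10854351 and 21446415 counts.

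Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). After filterByExpr by group, 18696 genes were scaled by TMM and fitted in 1 quasi-likelihood model with 12 group means over all 36 libraries. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called, in 16 pairwise comparisons and 4 interactions, which compare a drug effect between 36 h and 16 h or with and without the caspase inhibitor. Standard errors are the log2 change over the square root of the F statistic, and 95% intervals of the drug differences use the residual and prior degrees of freedom of the same model. Log CPM used a prior count of 2. Where a group had no count, the fold was bounded with a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with a 95% counting interval. Both cover counting error only, since reads copied in PCR are not independent molecules. All tests were two-sided.

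The comparisons, the 30 gene lists and the rule for named genes were fixed before the data were examined. Named are a fixed panel of genes of RAS, senescence, the BCL2 family, the sodium pump and stress. Also named are, per comparison, the 8 or 4 genes in each direction with the largest called log2 change, at least 5 CPM in the higher group and no overlap between the libraries of the compared groups, and up to 4 called members of each list with at least 1 CPM. Some genes that this rule names are not reported here. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives, and lists needed at least 3 tested members. Members of a list were also counted with p-values adjusted over the list alone, and that count is given where it differs from the count over all genes. Of the list genes, CCL3 and PECAM1 could not be matched. Near-identical copies, overlapping genes and antisense genes can share reads, since the strand setting is unknown.

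The model was tested on simulated data with 200 genes changed. For digoxin at 36 h it recovered 53.7% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97% of those changed 4-fold, and for the time interaction of digoxin 37.3%, 74.6% and 93.9%. False calls made up 3.66% of calls for digoxin at 36 h, 6.21% for senescence at 16 h and 6.8% for the time interaction, the last 2 above the 5% aimed at. These rates come from 200 changed genes among 18696, while the real test called 64% of genes with digoxin at 36 h. They may not hold for the reported comparisons. A list shifted by 0.5 on the log2 scale was called, and 0 other lists were called. Genes were simulated as independent there, so this does not test list calls that come from correlated members. Shared vehicle libraries were simulated in 20 data sets of unchanged groups.

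Alternatives were DESeq2 1.42.0, its size factors (RLE) in edgeR, scaling by library size, no filter on low counts, a block for the replicate number, a fit of the compared groups alone and leaving out each library. After the data were seen, a correction of GC content and length trends (lowess span 0.3) and a fit without the most deviating libraries (ouabain 16 h replicate 2 and proliferating 16 h replicate 2) were added. Splits of the 6 libraries of each pairwise comparison and 100 regroupings for each interaction, which exchange libraries between the times or inhibitor arms within drug-treated and within vehicle cells, were fitted. Figures were drawn with matplotlib 3.10.9.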

Results

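IMR90 ER:RAS fibroblasts are human lung fibroblasts that carry RAS fused to an oestrogen receptor domain, so that 4OHT switches RAS on and the cells enter senescence. RNA counts of 36 libraries covered proliferating cells with vehicle and senescent cells with vehicle, digoxin or ouabain, after 16 h, after 36 h and after 36 h with a caspase inhibitor, with n = 3 libraries in each of 12 groups. Values after ± are standard deviations (SD) for library-scaled counts (CPM) and standard errors (SE) for log2 fold changes. The first principal component held 61.8% of the variance and ordered the libraries from proliferating cells (112.9 to 120.5) over senescent vehicle cells (31.6 to 40.2) to the drug-treated cells (-25.8 to -96.9). The second component held 14.2% and the third 8.7%. Replicate 2 of ouabain at 16 h lay at -25.8 on the first component and the other ouabain libraries of that time at -56.7 and -56.5. Its median absolute log2 difference to the other replicates was 0.271. Replicate 2 of proliferating cells at 16 h had the highest such value, 0.375, and 2.521% of its counts came from mitochondrial ribosomal RNA, against 0.864% and 0.775% in the other libraries of that group. The labels do not say whether the 3 libraries of a group came from separate cultures, so all p-values measure the spread between these libraries, which may be technical.

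**Figure D1:**
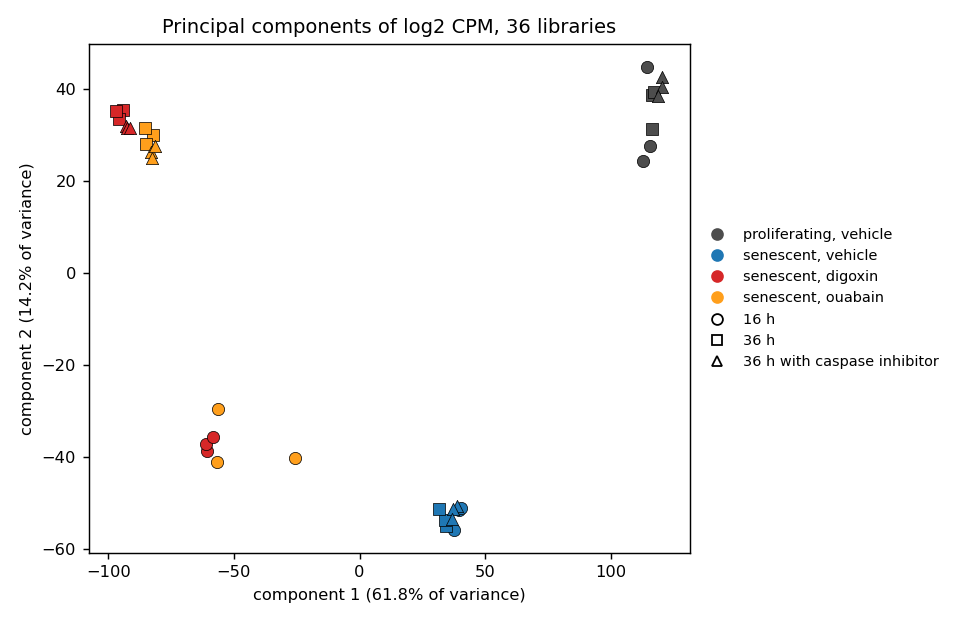
Principal components of the log2 CPM of the 36 libraries, each point a library coloured by state and treatment and shaped by time and inhibitor, and the axes giving the scores with their share of the variance. The first component (61.8%) runs from the proliferating libraries (112.9 to 120.5) to the drug-treated libraries (-25.8 to -96.9), and ouabain 16 h replicate 2 lies at -25.8.

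Senescent cells at 16 h carried a strong inflammatory secretory programme. CXCL8, the neutrophil chemokine, stood at 515 ± 75.9 CPM against 1.45 ± 0.653 CPM in proliferating cells, a 339-fold rise. IL1B, an inflammatory cytokine, rose from 0.332 ± 0.185 to 131 ± 8.47 CPM, TNFSF15, a cytokine of the TNF family, rose 398-fold, the matrix protease MMP10 242-fold and IL6 8.87-fold. IL1A, the other main interleukin-1, had 2 counts in all proliferating libraries of that time, and its ratio was 743 (95% counting interval 205 to 6140). CCL2, a monocyte chemokine, rose by a log2 change of 0.75 ± 0.22. Of 34 measured secreted factors of the senescence-associated secretory phenotype, 32 rose and 1 fell, and the same numbers were past the threshold when adjusted over the list alone (camera adjusted p = 4.55e-25, and 0.00125 with an estimated correlation).

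Cell division genes fell together in the same comparison. Of 36 genes of cell division and DNA replication, 34 fell and none rose (camera adjusted p = 2.18e-23, and 4.79e-06 with an estimated correlation). MKI67, the proliferation marker, was 53.4-fold lower at 1.46 ± 0.54 CPM against 79.9 ± 38.8 CPM, the mitotic kinesin KIF20A 37.4-fold lower, the nuclear lamina gene LMNB1 19-fold lower and cyclin A2 (CCNA2) 8.08-fold lower. The CDK inhibitors moved apart, with 3 of 7 higher and 3 lower. CDKN2B (p15) rose 13.2-fold from 17.7 ± 1.2 to 234 ± 3.38 CPM, CDKN2A (p16 and ARF) 2.73-fold and CDKN1A (p21) 2.17-fold. CDKN1C (-3.45 ± 0.5 on the log2 scale) and CDKN2C (-3.12 ± 0.3) fell. This list was not called (camera adjusted p = 0.44), and its median was 0.31 while its mean was -0.18. HRAS rose 2.32-fold. NRAS was at -0.19 ± 0.08, a call lost without the filter on low counts.

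Negative feedback genes of MAP kinase signalling, which RAS drives, rose in 12 of 14 cases and none fell (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.33e-09). DUSP6, a phosphatase of ERK, rose by a log2 change of 2.53 ± 0.08, DUSP4 by 2.64 ± 0.12, SPRY4 by 1.75 ± 0.09 and IER3 by 3.6 ± 0.14. Of 12 feedback targets of NF-kB, 10 rose and 1 fell, among them ICAM1 (27.3-fold higher), an adhesion molecule, and NFKBIZ (2.18 ± 0.11), an inhibitor-family protein of NF-kB (camera adjusted p = 3.51e-06, and 0.0425 with an estimated correlation). Of 22 p53 targets, 15 rose and 2 fell (camera adjusted p = 0.000132, and 0.0425 with an estimated correlation), with the stress cytokine GDF15 21.7-fold higher. All 5 measured survival genes of the BCL2 family passed the test, with 4 higher and 1 lower (camera adjusted p = 0.0073). BCL2A1 rose 50.7-fold (a log2 change of 5.66, and 7.06 without proliferating 16 h replicate 3), MCL1 3.26-fold and BCL2L1, which encodes BCL-XL, by a log2 change of 0.45 ± 0.07, while BCL2 fell by 1.26. Of 8 genes in the death receptor list, 5 rose and none fell (camera adjusted p = 0.00782). Among them were TNFRSF10D (1.8 ± 0.09), a decoy receptor for the death ligand TRAIL, and TNFRSF10B (1.32 ± 0.07), a death receptor for it. Smooth muscle type contractile genes fell in 11 of 12 cases (camera adjusted p = 1.68e-07), with CNN1 at -2.14 ± 0.13 and ACTA2 at -1.94 ± 0.1.

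Further groups moved at 16 h with camera calls that were lost with an estimated correlation. Lysosomal genes rose in 19 of 25 cases and 2 fell (20 and 3 adjusted over the list alone, camera adjusted p = 1.03e-08, and adjusted p = 0.0775 with an estimated correlation), led by the cholesterol exporter NPC1 (6.8-fold) and the protease CTSB (1.74 ± 0.06). Extracellular matrix genes fell in 15 of 23 cases and 2 rose (camera adjusted p = 5.58e-06, and adjusted p = 0.177 with an estimated correlation), with DCN at -3.25 ± 0.11 and COL3A1 at -1.96 ± 0.11. Mitochondrially encoded genes rose in 12 of 13 cases (camera adjusted p = 2.73e-05, and adjusted p = 0.222 with an estimated correlation), and nuclear genes of oxidative phosphorylation in 27 of 32 (camera adjusted p = 1.36e-05, and adjusted p = 0.416 with an estimated correlation). ATF4 stress genes rose in 19 of 24 cases and 3 fell (20 and 4 adjusted over the list alone, camera adjusted p = 4.13e-05, and adjusted p = 0.13 with an estimated correlation), and cholesterol synthesis genes rose in 15 of 20 and 2 fell (camera adjusted p = 0.000132, and adjusted p = 0.13 with an estimated correlation). Immediate early genes rose in 15 of 23 cases and 4 fell (camera adjusted p = 0.00113, and adjusted p = 0.273 with an estimated correlation), with PTGS2, the inducible cyclooxygenase, at 5.08 ± 0.21. Metallothioneins rose in 5 of 6 cases (camera adjusted p = 0.00128, and adjusted p = 0.0947 with an estimated correlation), glycolysis and hypoxia genes in 13 of 18 with 3 lower (camera adjusted p = 0.00383, and adjusted p = 0.284 with an estimated correlation) and ribosomal protein genes in 17 of 45 (16 adjusted over the list alone, camera adjusted p = 0.00171, and adjusted p = 0.62 with an estimated correlation). Reads of metallothioneins and ribosomal protein genes can be shared with near-identical copies.

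Other lists were not called at 16 h by camera. Interferon-stimulated genes had 2 members higher, including CXCL10 (3.56 ± 0.38), and 9 lower, including IFIT1 (-2.55 ± 0.46), with an adjusted p of 0.257. Heat shock genes had 9 higher and 4 lower (adjusted p = 0.447), with a median of 0.3 and a mean of -0.11. Genes of the Na/K-ATPase had 3 higher and 1 lower (adjusted p = 0.431, median 0.22, mean -0.3). Camera also gave no call for pro-apoptotic BCL2 family genes (4 higher, 1 lower, adjusted p = 0.254), caspases (4 and 2, adjusted p = 0.52), unfolded protein response genes (7 and 2, 8 and 2 adjusted over the list alone, adjusted p = 0.0829), NRF2 targets (10 and 1, adjusted p = 0.0929) and osmotic stress genes of NFAT5 (1 and 4, adjusted p = 0.431). Markers of other cell types were few and not called: 3 epithelial (0 higher, 1 lower, adjusted p = 0.255), 4 endothelial (2 higher, 1 lower, adjusted p = 0.431) and 6 leukocyte genes (2 higher, 0 lower, 1 higher adjusted over the list alone, adjusted p = 0.515).

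The edgeR quasi-likelihood test called 9651 of 18696 genes in senescent against proliferating cells at 16 h, 4945 higher and 4706 lower, and 1249 and 2055 of these changed by 1 or more on the log2 scale. Among the largest changes, LCE1F was at least 238-fold higher, and CEMIP, a hyaluronan-binding protein, was 53.7-fold lower. At 36 h, 9823 genes were called, 5001 higher and 4822 lower. TNFSF15 was then 582-fold higher, IL1B 359-fold, CXCL8 387-fold, ICAM1 44.2-fold, IL6 11.5-fold, CDKN2B 7.68-fold and HRAS 2.23-fold, and MKI67 was 21.9-fold lower. Of the secreted factors 32 rose and 2 fell (camera adjusted p = 1.21e-23, and 0.00176 with an estimated correlation), of the cell division genes 35 fell and 1 rose (camera adjusted p = 1.21e-18, and 3.14e-05 with an estimated correlation), and MAP kinase feedback genes rose in 13 of 14 cases (camera adjusted p = 2.66e-10). With the caspase inhibitor at 36 h, 9787 genes were called, 4979 higher and 4808 lower, with MKI67 31.8-fold lower. In that arm interferon-stimulated genes fell in 13 of 19 cases and 1 rose (1 and 14 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.523 with an estimated correlation and 0.0582 with scaling by library size), with IFIT2 at -3.18 ± 0.22. These counts rest on a scaling that takes most genes as unchanged. Scaled by library size alone the median log2 change moved by -0.11 at 16 h and by -0.15 in both 36 h arms, and the split became 3849 higher and 5592 lower, 3780 and 6107, and 3642 and 6052.

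**Figure D2:**
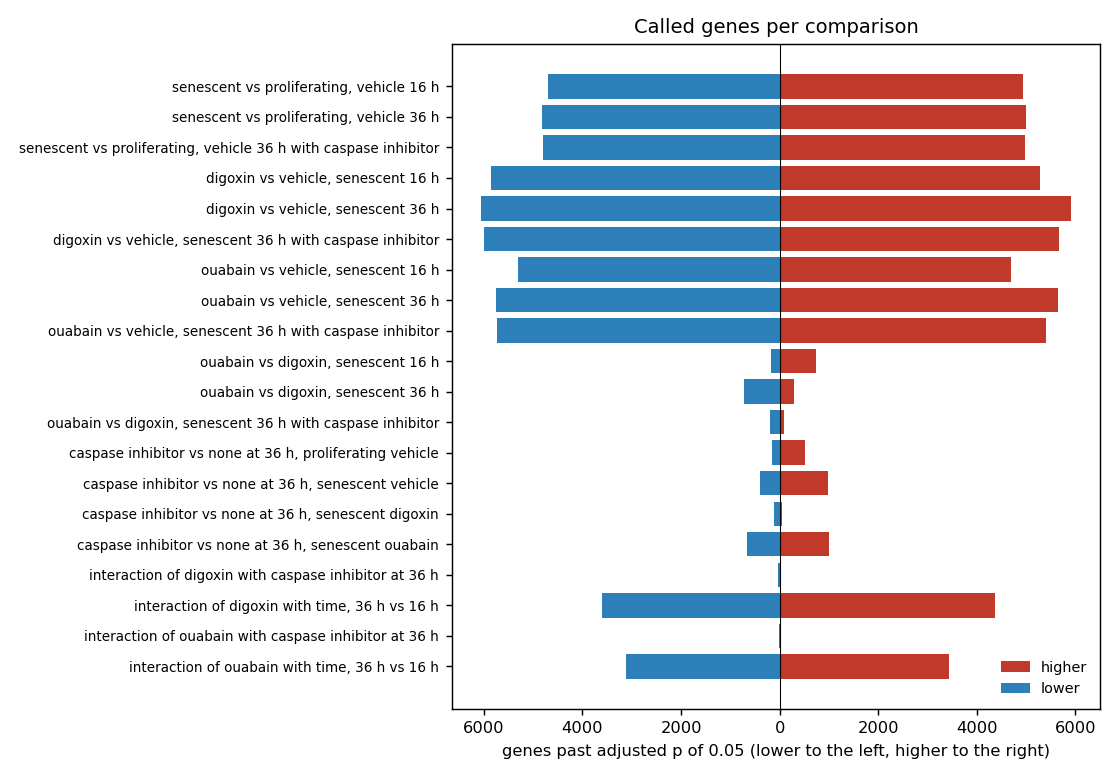
Number of genes past an adjusted p of 0.05 in each comparison (edgeR quasi-likelihood test, 18696 genes tested), higher to the right and lower to the left of 0. Digoxin at 36 h gave 5909 higher and 6054 lower genes, and the interactions with the caspase inhibitor gave 46 (digoxin) and 28 (ouabain) in all.

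Digoxin, a cardiac glycoside that blocks the Na/K-ATPase, switched on immediate early genes in senescent cells within 16 h. FOS, a transcription factor of the AP-1 complex, rose 148-fold from 0.893 ± 0.0866 to 134 ± 13.8 CPM, DUSP2, a MAP kinase phosphatase, rose 360-fold to 110 ± 4.97 CPM, ARC 182-fold (a log2 change of 7.51, and 8.51 without senescent vehicle 16 h replicate 2) and EGR1 19.1-fold. Of 23 immediate early genes, 20 rose and 1 fell (camera adjusted p = 1.04e-11, and adjusted p = 0.061 with an estimated correlation). Genes of the pump itself rose, with ATP1B3 at 1.06 ± 0.09 and ATP1B1 at 0.77 ± 0.09. In all, 5 of 7 pump genes rose (6 adjusted over the list alone, camera adjusted p = 0.00773, and adjusted p = 0.0872 with an estimated correlation). FXYD5, a regulator of the pump among them, was at 0.29 ± 0.07 and turned to -0.03 with scaling by library size. All 7 osmotic stress genes rose (camera adjusted p = 1.9e-05, and adjusted p = 0.061 with an estimated correlation), including NFAT5, the transcription factor of this response (2.47 ± 0.24), and the taurine transporter SLC6A6 (2.27 ± 0.12).

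Stress response genes also rose with digoxin at 16 h. ATF3 was 9.42-fold higher, DDIT3 2.83-fold and the haem-degrading enzyme HMOX1 5.07-fold, and PPP1R15A, a phosphatase subunit that restores translation, was at 3.4 ± 0.11. ATF4 stress genes rose in 19 of 24 cases and 1 fell (camera adjusted p = 4.04e-07, and adjusted p = 0.0872 with an estimated correlation), lysosomal genes in 24 of 25 with none lower (camera adjusted p = 4.82e-12, and adjusted p = 0.0694 with an estimated correlation), and p53 targets in 16 of 22 with 4 lower (17 and 4 adjusted over the list alone, camera adjusted p = 0.000356, and adjusted p = 0.0872 with an estimated correlation). The secretory genes rose further in 23 of 34 cases and 4 fell (camera adjusted p = 5.28e-06, and adjusted p = 0.148 with an estimated correlation). IL11 rose 20.2-fold, IL6 4.64-fold, CXCL8 3.81-fold, IL1A 3.51-fold and IL1B 2.08-fold, and CCL2 fell by 1.01 on the log2 scale. NF-kB feedback genes rose in 9 of 12 cases and 1 fell (camera adjusted p = 0.000159, and adjusted p = 0.115 with an estimated correlation). Caspase and apoptosome genes fell in 7 of 10 cases and 2 rose (camera adjusted p = 0.0492, adjusted p = 0.294 with an estimated correlation and 0.0917 with scaling by library size), with CASP8 at -2.08 ± 0.22 and APAF1 at -1.71 ± 0.15. HRAS rose 2.63-fold while MYC (-0.95 ± 0.11) fell, and NRAS was at -0.27 ± 0.08, a call lost after a correction for GC content and length. CDKN1A rose 1.98-fold, and CDKN2B (-0.05 ± 0.07) and MKI67 (0.14 ± 0.39) were not called.

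At 36 h the digoxin response was wider. FOS was 168-fold higher, ATF3 29.2-fold, PPP1R15A 12.1-fold, and ARC stood at 664 ± 146 against 1.23 ± 0.332 CPM, a 543-fold rise. NRF2 targets, the genes of the antioxidant response, rose in 14 of 16 cases and 1 fell (camera adjusted p = 1.04e-07, and adjusted p = 0.08 with an estimated correlation), with HMOX1 25.1-fold higher at 560 ± 111 CPM and OSGIN1 at 4.26 ± 0.12. Immediate early genes rose in 21 of 23 cases and ATF4 stress genes in 21 of 24 (camera adjusted p = 6.99e-10 and 6.05e-08, each with an adjusted p of 0.08 under an estimated correlation). Cholesterol synthesis genes fell in 17 of 20 cases and 1 rose (camera adjusted p = 2.91e-06, and adjusted p = 0.107 with an estimated correlation). The synthesis enzyme MVK was 7.43-fold lower, and the gene that rose was INSIG1 (2.85 ± 0.14), which restrains this pathway. Extracellular matrix genes fell in 16 of 23 cases and 3 rose (3 and 17 adjusted over the list alone, camera adjusted p = 0.000153, and adjusted p = 0.318 with an estimated correlation), with COL1A1 at -2.09 ± 0.12. Contractile genes fell in 8 of 12 cases (9 adjusted over the list alone, camera adjusted p = 0.00147, and adjusted p = 0.231 with an estimated correlation).

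The secretory genes split at 36 h of digoxin. IL24 rose 212-fold, CXCL2 68.5-fold, IL6 14.9-fold, CXCL8 11.4-fold to 8050 ± 707 CPM and IL1B 7.57-fold to 1750 ± 190 CPM, while CCL2 fell 6.78-fold. In all 23 of 34 rose and 7 fell (camera adjusted p = 0.00016, and adjusted p = 0.284 with an estimated correlation). CDKN2B, raised in senescence, fell 4.03-fold with digoxin, and LMNB1, lowered in senescence, rose 6.45-fold. Among the cell division genes 12 rose and 14 fell (camera adjusted p = 0.961), with a median of -0.25 and a mean of 0.1, and MKI67 fell by 1.56. Over all 18696 tested genes 5909 rose and 6054 fell. HRAS rose 3.77-fold, and CDKN1A rose by 0.71 ± 0.07. Large changes included FGF19, a growth factor (ratio 1790, 95% counting interval 494 to 14800), PROK2, a secreted peptide that was at least 324-fold higher, and the chemokine CXCL10, which was 26.8-fold lower. Endothelial marker genes had 2 members higher and 2 lower, KDR, a receptor of VEGF, being 165-fold higher, and the leukocyte markers CD14 (3.7 ± 0.43) and ITGAM (ratio 36.6, 95% counting interval 9.6 to 310) were higher. Neither list was called (camera adjusted p = 0.972 for the endothelial list, which had a median of -0.45 and a mean of 1.28, and 0.244 for the leukocyte list).

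The test called 11144 genes with digoxin at 16 h (5285 higher, 5859 lower) and 11963 at 36 h (5909 higher, 6054 lower). With the caspase inhibitor at 36 h it called 11672 (5673 higher, 5999 lower), and FOS was 328-fold higher, HMOX1 was at 4.68 ± 0.14, IL6 was at 3.55 ± 0.19 and CDKN2B was at -2.05 ± 0.07. In that arm cholesterol synthesis genes fell in 19 of 20 cases (camera adjusted p = 1.67e-07), NRF2 targets rose in 14 of 16 (camera adjusted p = 1.99e-07) and ATF4 stress genes in 21 of 24 (camera adjusted p = 1.08e-09), each with an adjusted p of 0.0556 under an estimated correlation. Scaling by library size alone moved the median log2 change by -0.32, -0.31 and -0.24 in these arms and gave 2937 higher and 8199 lower, 4278 and 8406, and 4313 and 7841 genes, so the balance between higher and lower genes is relative to the scaling.

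Ouabain is also a cardiac glycoside, with a rhamnose as its sugar in place of the chain of digitoxose sugars of digoxin. At 16 h FOS was 80.2-fold higher, DUSP2 199-fold, EGR1 12.5-fold, MCL1 2.82-fold, PMAIP1 1.87-fold and HRAS 2.12-fold. These folds include replicate 2, where FOS stood at 45.9 CPM against a mean of 85.8 CPM in replicates 1 and 3. PMAIP1 stood at 315 CPM there, against 432 and 424 CPM. Immediate early genes rose in 20 of 23 cases and 1 fell (camera adjusted p = 1.17e-12, and 0.0297 with an estimated correlation), ATF4 stress genes rose in 20 of 24 (camera adjusted p = 2.55e-11, and 0.0297 with an estimated correlation), all 7 osmotic stress genes rose (camera adjusted p = 5.23e-06, and 0.0297 with an estimated correlation) and lysosomal genes rose in 23 of 25 (camera adjusted p = 1.17e-12, and 0.0447 with an estimated correlation). Secretory genes rose in 24 of 34 cases and 3 fell (camera adjusted p = 7.19e-07, and adjusted p = 0.106 with an estimated correlation). The transcription factor OSR1 was at -2.68 ± 0.34 with 4.52 ± 6 CPM, and that SD exceeds the mean because of replicate 2. The test called 9990 genes (4688 higher, 5302 lower), and 2784 and 7769 when scaled by library size, which moved the median by -0.28.

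At 36 h of ouabain, IL24 was 210-fold higher, HMOX1 22.7-fold, IL6 8.77-fold, CXCL8 8.61-fold, IL1B 5.86-fold and HRAS 4.11-fold. CXCL10 was 32.9-fold lower, CCL2 was at -2.76 ± 0.25, CDKN2B at -1.81 ± 0.07 and LMNB1 at 2.62 ± 0.22. NRF2 targets rose in 15 of 16 cases (camera adjusted p = 8.48e-09, and 0.0454 with an estimated correlation), ATF4 stress genes in 21 of 24 (camera adjusted p = 4.9e-10, and 0.0454 with an estimated correlation), and cholesterol synthesis genes fell in 17 of 20 with 1 higher (1 and 18 adjusted over the list alone, camera adjusted p = 2.71e-06, and adjusted p = 0.0874 with an estimated correlation). Extracellular matrix genes fell in 16 of 23 cases and 4 rose (camera adjusted p = 0.000343, and adjusted p = 0.342 with an estimated correlation). The test called 11403 genes (5642 higher, 5761 lower), and 11122 with the caspase inhibitor (5398 higher, 5724 lower). Scaled by library size alone the splits were 4348 and 7575, and 4162 and 7385, with the median moved by -0.22 and -0.21. With the inhibitor, immediate early genes rose in 21 of 23 cases (camera adjusted p = 1.2e-11, and 0.0359 with an estimated correlation), and FOS was at 8.54 ± 0.38 and HMOX1 at 4.64 ± 0.14.

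**Figure D3:**
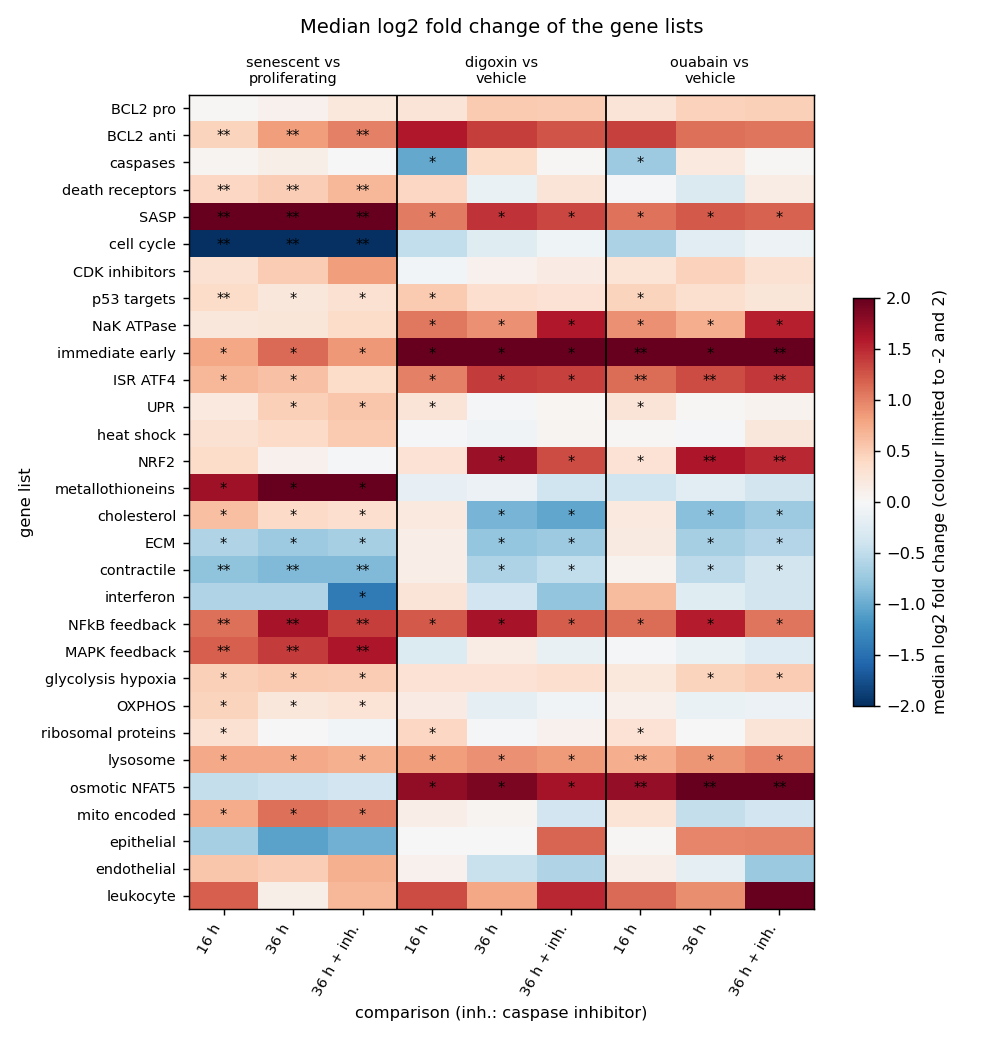
Median log2 fold change of each fixed gene list (vertical) in senescence and with each drug at each time (horizontal), with colours limited to -2 and 2. One star marks a camera call and a double star a call that holds with an estimated correlation, and the secretory list has a median of 4.56 in senescence at 16 h.

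The doses of the drugs are not given in the sources used here, so differences between digoxin and ouabain can stem from dose as well as from the drug. Across genes their log2 changes correlated with r = 0.944 at 16 h, 0.957 at 36 h and 0.961 at 36 h with the inhibitor. Both drugs share their vehicle libraries. In simulated unchanged data this sharing alone gave r = 0.469, 0.43 and 0.454, and genes are not independent replicates. Those data hold noise only, so their r is not the part of the observed r that is due to sharing. The covariance was 1.141, 1.655 and 1.776, against 0.0599, 0.0557 and 0.0753 in the simulation. Without shared vehicles, digoxin at 16 h and ouabain at 36 h correlated with r = 0.68, and digoxin at 36 h and ouabain at 16 h with r = 0.706, where simulation gave -0.003. At 36 h, 5074 genes rose and 5159 fell with both drugs, and 6 moved in opposite directions.

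The 95% interval of the difference between the drugs lay within -1 and 1 on the log2 scale for 74.9% of the tested genes at 16 h, 75.9% at 36 h and 75.6% with the inhibitor. HMOX1 differed by a log2 change of -0.15 at 36 h (95% interval -0.38 to 0.08), ATF3 by -0.1 (-0.38 to 0.17) and PMAIP1 by -0.22 (-0.44 to 0). Direct tests found differences in some genes. At 16 h 923 genes were called, 739 higher and 184 lower with ouabain, with the cholesterol synthesis enzyme SQLE at 1.13 ± 0.12 (0.8 without ouabain 16 h replicate 2). That count fell to 127 without ouabain 16 h replicate 2 and rose to 1693 without replicate 1. A fit of these 6 libraries alone called 0 genes, with 2110 at an unadjusted p under 0.05, and DESeq2 in a fit of all 36 libraries called 1218 genes. At 36 h 1003 genes were called, 284 higher and 719 lower. These changes followed GC content (rho = 0.32), and 481 of the 1003 genes stayed called after GC and length trends were removed, with the median absolute log2 change falling from 0.38 to 0.28. With ouabain against digoxin, IL6 was at -0.76 ± 0.16, CXCL2 at -0.72 ± 0.13, CXCL3 at -0.93 ± 0.16 and PTGS2 at -0.75 ± 0.12. Leaving out 1 of the 6 libraries gave 374 (ouabain 36 h replicate 1) to 655 (ouabain 36 h replicate 3) genes. Of 34 secretory genes 10 were lower and none higher (13 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.00133, and adjusted p = 0.495 with an estimated correlation). Scaled by library size alone the split at 36 h turned to 704 higher and 294 lower. With the inhibitor 271 genes were called, 82 higher and 189 lower (92 without digoxin replicate 3 of that arm, 305 without replicate 2), with IL6 at -1.05 ± 0.16 and CXCL1 at -1.05 ± 0.19. There, cholesterol synthesis genes were higher with ouabain in 8 of 20 cases and lower in none (15 and 0 adjusted over the list alone, camera adjusted p = 4.83e-15, and 0.0102 with an estimated correlation), with MSMO1 at 0.52 ± 0.09.

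**Figure D4:**
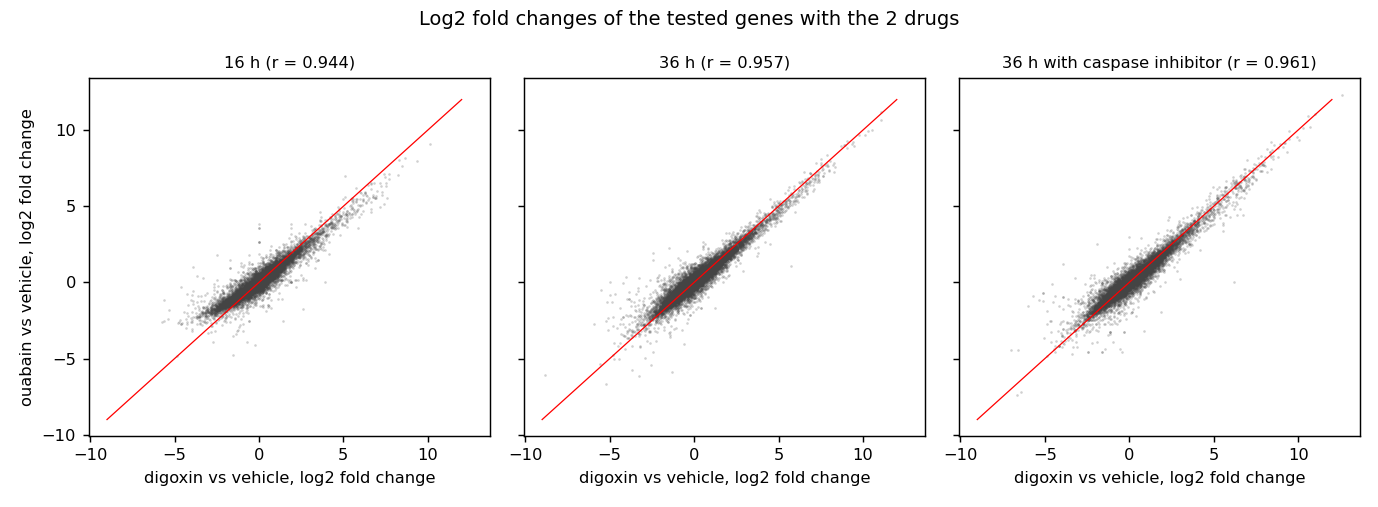
Log2 fold change of each tested gene with digoxin (horizontal) and with ouabain (vertical) against the shared senescent vehicle libraries at 16 h, 36 h and 36 h with the caspase inhibitor. The red line marks equal changes, and r across genes was 0.944, 0.957 and 0.961.

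Genes of the BCL2 family moved on both sides of cell death control with the drugs. PMAIP1 (NOXA), which binds and opposes MCL1, rose 2.01-fold with digoxin at 16 h to 418 ± 6.86 CPM against 208 ± 8.51 CPM in senescent vehicle cells, and rose 4.07-fold at 36 h to 693 ± 12.8 against 171 ± 6.64 CPM. BCL2L11 (BIM) rose 6.61-fold with digoxin and 7.01-fold with ouabain at 36 h and was not called at 16 h (0.16 ± 0.3 and 0.1 ± 0.3). BMF was lower at 16 h (-1.84 ± 0.24 with digoxin, -1.18 ± 0.21 with ouabain) and higher at 36 h (1.25 ± 0.16 and 1.62 ± 0.16). BBC3 (PUMA) rose 2.74-fold with digoxin at 16 h, and BAD fell 2.41-fold at 36 h. Among the survival genes, MCL1 rose 3.29-fold with digoxin at 16 h to 2290 ± 43.5 CPM and 2.62-fold at 36 h, BCL2A1 rose by 1.6 ± 0.12 and 2 ± 0.12, and BCL2L1 fell by 0.3 and 0.73. With digoxin at 36 h, 5 of 10 pro-apoptotic members rose and 4 fell (camera adjusted p = 0.666), and 4 of 5 survival members rose and 1 fell (camera adjusted p = 0.282), so neither list was called. BIK was not tested because of low counts.

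**Figure D5:**
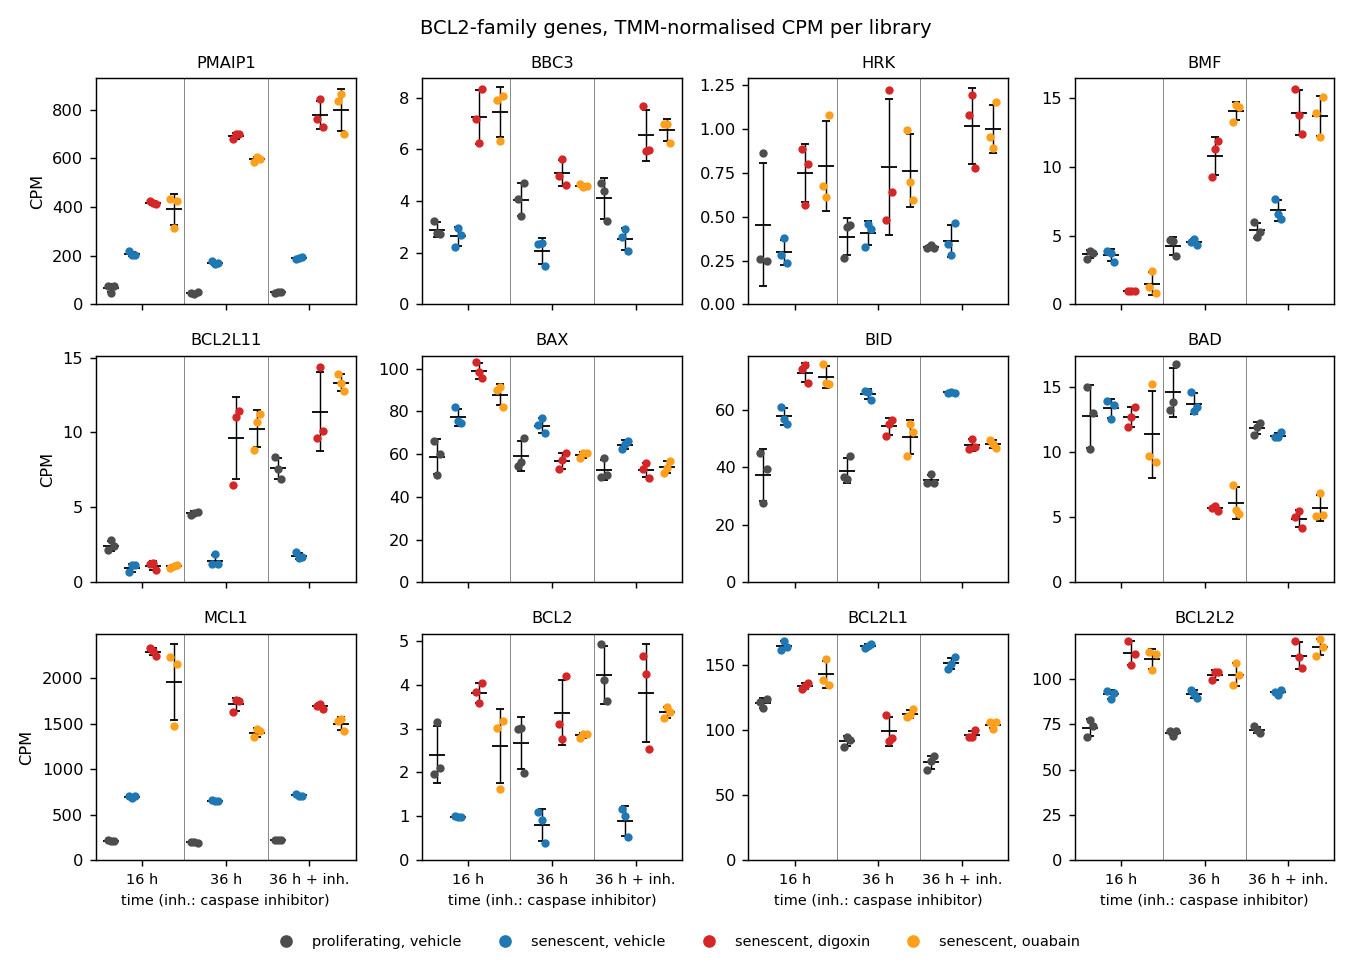
CPM (vertical) of 12 genes of the BCL2 family in each library (points, coloured by state and treatment) by time and inhibitor (horizontal), with the mean and SD of the 3 libraries of each group. PMAIP1 rises from 171 CPM in senescent vehicle cells to 693 CPM with digoxin at 36 h, while BCL2L1 falls from 164 to 99.2 CPM.

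Drug effects changed between 16 h and 36 h in many genes by the test of the difference itself. For digoxin 7978 genes were called (4376 with a higher and 3602 with a lower log2 change at 36 h) and for ouabain 6562 (3443 and 3119). The ouabain values include 16 h replicate 2, which lay nearer to vehicle on the first component than the other libraries of its group. PMAIP1 gained 1.02 ± 0.15 with digoxin and 0.9 ± 0.15 with ouabain, BCL2L11 2.56 ± 0.37 and 2.71 ± 0.37, and BMF 3.08 ± 0.29 and 2.8 ± 0.26, while MCL1 was at -0.33 ± 0.12 and -0.39 ± 0.12, calls that were lost without digoxin 36 h replicate 1 (-0.3) and without ouabain 16 h replicate 1 (-0.28). LMNB1 gained 3.35 ± 0.42 and 3.63 ± 0.43, and CDKN2B was at -1.96 ± 0.1 and -2.08 ± 0.1. Cholesterol synthesis genes were lower at 36 h than at 16 h relative to vehicle in 16 of 20 cases for each drug (18 for digoxin adjusted over the list alone). The list was called for digoxin (camera adjusted p = 4.77e-10, and adjusted p = 0.069 with an estimated correlation) and for ouabain (camera adjusted p = 5.86e-12, and 0.0319 with an estimated correlation). NRF2 targets were higher in 14 and 13 of 16 cases (14 for ouabain adjusted over the list alone, camera adjusted p = 5.96e-06 and 2.16e-08, with an adjusted p of 0.164 and 0.0742 under an estimated correlation), with GCLM, an enzyme of glutathione synthesis, at 2.52 ± 0.12 and 2.17 ± 0.12. Extracellular matrix genes were lower in 19 and 18 of 23 cases (camera adjusted p = 2.08e-09 and 5.67e-09, with an adjusted p of 0.164 and 0.249 under an estimated correlation). Caspase genes were higher in 6 and 4 of 10 cases (7 and 4 adjusted over the list alone, camera adjusted p = 0.0226 and 0.0337, with an adjusted p of 0.386 and 0.351 under an estimated correlation), with APAF1 at 2.14 ± 0.2 and 1.65 ± 0.2.

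Changes in senescence and with the drugs were compared gene by gene. Of 5001 genes higher in senescence at 36 h, 1833 fell and 1951 rose with digoxin, where independent lists would give 1619 and 1581. Of 4822 genes lower in senescence, 1215 rose, where 1524 would be given by independent lists. At 16 h the numbers that rose in senescence and fell with the drug lay under those of independent lists, 1456 against 1550 with digoxin and 1283 against 1402 with ouabain. The share of genes raised in senescence that fell with digoxin was 29.4% at 16 h and 36.7% at 36 h. Across genes, senescence and digoxin changes correlated with r = 0.122 at 16 h and 0.102 at 36 h. The shared vehicle libraries alone gave -0.481 and -0.453 in simulated unchanged data, which hold noise only. The covariance was 0.16 at both times, against -0.0604 and -0.0553 in the simulation. With ouabain at 36 h, 1801 genes raised in senescence fell, where 1541 would be given by independent lists.

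At 36 h the inhibitor arm and a batch of libraries cannot be told apart, since the labels give no batch. In drug-treated cells of that arm, NF-kB feedback genes were lower than without the caspase inhibitor. With digoxin 9 of 12 fell and none rose (11 adjusted over the list alone, camera adjusted p = 4.71e-28, and 4.26e-05 with an estimated correlation), and with ouabain 11 of 12 (12 adjusted over the list alone, camera adjusted p = 1.27e-20, and 0.000407 with an estimated correlation). NFKBIZ fell from 355 ± 8.13 to 144 ± 9.19 CPM with digoxin and from 258 ± 31.1 to 100 ± 5.42 CPM with ouabain. IL6 was at -1.18 ± 0.16 and -1.46 ± 0.16, TNFAIP3, which restrains NF-kB, at -0.92 ± 0.1 and -1.06 ± 0.1, and CD83 at -1.26 ± 0.18 and -1.19 ± 0.18. In senescent vehicle cells 5 of these 12 genes fell (6 adjusted over the list alone, camera adjusted p = 5e-06, and adjusted p = 0.126 with an estimated correlation), with TNFAIP3 at -0.85 ± 0.11 and IL6 at -0.83 ± 0.2. Cholesterol synthesis genes rose in 10 of 20 cases with ouabain and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 2.86e-11, and 0.0236 with an estimated correlation), with MSMO1 at 0.89 ± 0.09. In proliferating cells 8 of 20 rose (10 adjusted over the list alone, camera adjusted p = 1.69e-10, and adjusted p = 0.0573 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at 0.6 ± 0.08. The list tests were not run with the correction of GC content and length trends, under which most inhibitor calls in vehicle cells were lost.

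The test called 671 genes for the inhibitor in proliferating vehicle cells (515 higher, 156 lower), 1385 in senescent vehicle cells (985 and 400), 164 with digoxin (57 and 107) and 1662 with ouabain (992 and 670). With scaling by library size alone the balance turned in proliferating cells (186 higher, 281 lower), in senescent vehicle cells (482 and 657) and with ouabain (664 and 991), with the median moved by -0.06, -0.07 and -0.06. The calls in vehicle cells also fell to 157 and 328 when trends of GC content and length were removed, a step added after the data were seen. Leaving out 1 of the 6 libraries gave 129 (proliferating with inhibitor, replicate 1) to 676 genes in proliferating cells, 527 (senescent vehicle with inhibitor, replicate 1) to 870 in senescent vehicle cells, 94 (digoxin 36 h replicate 2) to 113 with digoxin and 765 (ouabain with inhibitor, replicate 2) to 1239 with ouabain. Drug effects were then compared between the arms with and without the inhibitor. For digoxin 46 genes were called (3 with a higher and 43 with a lower log2 change with the inhibitor) and for ouabain 28 (12 and 16). NFKBIZ was at -0.86 for digoxin and -0.92 for ouabain. Leaving out 1 of the 12 libraries gave 2 (senescent vehicle with inhibitor, replicate 1) to 27 genes for digoxin and 8 (ouabain with inhibitor, replicate 2) to 20 for ouabain. The NF-kB list was called for ouabain, with 1 of 12 genes lower (8 adjusted over the list alone, camera adjusted p = 1.16e-11, and 0.0127 with an estimated correlation). It was also called for digoxin, with 2 lower (5 adjusted over the list alone, camera adjusted p = 1.05e-06, and adjusted p = 0.145 with an estimated correlation).

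HRAS reads rose with senescence and again with both drugs. HRAS stood at 553 ± 39.5 CPM in proliferating cells, 1240 ± 7.39 CPM in senescent vehicle cells, 4660 ± 280 CPM with digoxin and 5070 ± 116 CPM with ouabain at 36 h. ESR1, the oestrogen receptor gene, chosen after its values were seen, stood at 99 ± 4.78, 238 ± 6.89, 988 ± 50.6 and 888 ± 89.3 CPM in the same groups. The ratio of HRAS to ESR1 lay between 4.52 and 5.72 over the 12 groups while each gene ranged over 11.4-fold and 10.5-fold. Within groups the deviations of the 36 libraries correlated with r = 0.57 and rho = 0.51 (permutation p = 0.007), and r was 0.64 without the 2 libraries farthest from the median. The r of 0.57 exceeded that of 90.1% of 10759 genes. Within groups, other genes thus followed HRAS as closely over all 36 libraries, and the permutation p does not show a link particular to ESR1. Without ouabain 16 h replicate 2 and proliferating 16 h replicate 2, a step chosen after this result, the r of ESR1 was 0.66 and its percentile 99.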

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

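The results below were selected because the test of a difference between drug effects, over time or with the caspase inhibitor, passed its threshold, or because a gene of the fixed panel moved in opposite directions at 16 h and 36 h. The regroupings of the libraries were planned, but what they would show was written down only after the counts were seen.

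The effect of digoxin differed between 36 h and 16 h in 7978 genes and that of ouabain in 6562. With digoxin the largest differences in log2 change were IL1RN at 7.83, LINC02957 at 7.59, ZIC2 at 7.36 and APLN at 6.22 on the higher side, and VWA5A at -3.25, CXCL10 at -3.12, AREG at -3.07 and CFAP70 at -2.96 on the lower side. With ouabain they were LINC02957 at 7.68, IL1RN at 6.7, UCA1 at 6.57 and APLN at 6.25, and CXCL10 at -4.42, DNAI3 at -3.09, AREG at -3.02 and VWA5A at -2.92. Among panel genes that moved in opposite directions at the 2 times, the changes differed with digoxin by 0.51 for NRAS, -0.61 for BID, 3.08 for BMF and -0.72 for BAX. Of these, NRAS turned to -0.07 at 36 h with library size scaling, under which BID and BAX lost their calls at 16 h (0.02 and 0.04), and with the GC correction NRAS lost its call at 16 h (-0.06) and NRAS, BID and BAX lost theirs at 36 h (0.13, -0.11 and -0.09). With ouabain they differed by -2.08 for CDKN2B, 3.63 for LMNB1, -0.68 for BID and 2.8 for BMF. At 16 h CDKN2B turned to -0.01 and BID lost its call (0.02) with library size scaling, so opposite directions are not shown for NRAS, BID, BAX and CDKN2B. LMNB1 stayed lower at 16 h with the GC correction but lost its call, so opposite directions are not shown for it under that setting. It had only 5, 17 and 5 counts with ouabain at 16 h, against 12, 29 and 22 with vehicle. In fits of the 12 libraries alone, the real grouping gave 9710 genes for digoxin and 6454 for ouabain. Of 100 splits, the real one included, 2 gave as many genes for digoxin (highest other 10253) and 2 for ouabain (highest other 7212). The splits exchange libraries between the times within drug-treated and within vehicle cells. The highest other count came for each drug from the split that reversed the times in vehicle cells alone, and splits that kept the drug-treated libraries in place gave 9219 or more genes for digoxin and 5912 or more for ouabain. The splits follow the time effect itself, a structure of the samples, so they do not test whether chance gives these counts.

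The effect of digoxin differed with the caspase inhibitor in 46 genes, among them MEG9 at 1.13 and ANPEP at 0.6 on the higher side and MCTP2 at -1.33, CHRM2 at -1.01, ZBTB10 at -0.9 and NFKBIZ at -0.86 on the lower side. That of ouabain differed in 28, among them RNF227 at 1.47, KLF4 at 1.39 and HBEGF at 0.9, and NFKBIZ at -0.92, LRCH2 at -0.9, EDN1 at -0.87 and ZNF212 at -0.85. In fits of the 12 libraries alone the real grouping gave 646 and 644 genes. Of 100 splits, the real one included, 9 gave as many for digoxin (highest other 4104) and 5 for ouabain (highest other 5584). The highest came for each drug from the split that reversed the inhibitor arms in vehicle cells alone, which turns the effect of the inhibitor arm into a difference. This is a structure of the samples, so these splits do not test chance either, and they were run on fits that call more genes than the reported 46 and 28.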

How the results depend on the processing

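The GC content and length correction and the fit without both deviating libraries were chosen after the data were seen. The counts of the comparisons of senescence, digoxin and ouabain with their controls and of the time interactions stayed within 1.5 times of the reported counts under the alternatives run, whereas those of ouabain against digoxin, of the inhibitor and of the inhibitor interactions moved, and the cause was not tested unless given. Of 1795 values of named genes, 1666 kept their side of the threshold with library size scaling, 1650 with the GC correction and 1765 with DESeq2.

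Under library size scaling these values turned in sign: with digoxin at 16 h FXYD5 (-0.03), at 36 h ROBO4 (-0.09), NRAS (-0.07), BAK1 (-0.2) and BCL2L2 (-0.16), with the inhibitor NRAS (-0.05), and with ouabain at 16 h CDKN2B (-0.01) and FXYD5 (-0.06), at 36 h FXYD5 (-0.03), BAK1 (-0.22) and BCL2L2 (-0.07). Under the GC correction these turned: BAK1 with digoxin and the inhibitor (0.21), LAMP2 for the inhibitor in senescent vehicle cells (0) and MT2A in the time interaction of digoxin (0.02). They are small changes against a shift of the median that the scaling itself sets.

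Without both deviating libraries, ouabain against digoxin called 281 genes at 16 h, 2721 at 36 h and 1132 with the inhibitor. The inhibitor called 2453 genes in proliferating, 3115 in senescent vehicle, 710 in digoxin and 3271 in ouabain-treated cells, and its interactions 388 (digoxin) and 203 (ouabain). In fits of the compared groups alone, ouabain against digoxin called 0 genes at 16 h, 2150 at 36 h and 933 with the inhibitor, the inhibitor called 5562 in senescent vehicle, 434 in digoxin and 2786 in ouabain-treated cells, and its interactions 646 and 644. The spread is then estimated from fewer libraries. DESeq2 called 518 genes for ouabain against digoxin with the inhibitor, 1430 and 300 for the inhibitor in proliferating and digoxin-treated cells, and 157 and 69 for its interactions. Without the filter the inhibitor called 415 and 668 genes in proliferating and senescent vehicle cells and 22 and 86 in its interactions. With the GC correction the inhibitor called 157, 328 and 250 genes in proliferating, senescent vehicle and digoxin-treated cells and 10 and 52 in its interactions. The digoxin interaction with the inhibitor gave 11 genes with RLE and 12 with library size, and that of ouabain 17 with the replicate block.

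Correlations between the drugs moved in fits of the compared groups alone to 0.975 at 36 h, 0.981 with the inhibitor, 0.707 for digoxin at 16 h with ouabain at 36 h and 0.742 for digoxin at 36 h with ouabain at 16 h, and the counts of genes moved in senescence and back with ouabain at 16 h to 756 and 553.

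Of the list tests, camera called 54 of 90 in senescence, 33 with digoxin, 36 with ouabain, 23 for ouabain against digoxin, 26 of 120 for the inhibitor, and 13 and 22 of 60 for the inhibitor and time interactions. With an estimated correlation these were 22, 0, 11, 1, 3, 1 and 1. With fry they were 67 for digoxin, 68 for ouabain, 10 for ouabain against digoxin, 5 for the inhibitor interactions and 35 for the time interactions.

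Leaving out 1 library gave 8594 to 10157 genes in senescence at 16 h, 8993 to 9437 at 36 h and 8897 to 9143 with the inhibitor, 10265 to 10768, 11265 to 11371 and 10938 to 11086 for digoxin, and 8697 to 10313 (without replicate 2), 10588 to 10890 and 10281 to 10529 for ouabain. It gave 127 (without ouabain 16 h replicate 2) to 1693, 374 to 655 and 92 to 305 for ouabain against digoxin, 129 to 676, 527 to 870, 94 to 113 and 765 to 1239 for the inhibitor in proliferating, senescent vehicle, digoxin and ouabain-treated cells, 2 to 27 and 8 to 20 for its interactions, and 7297 to 7746 and 5891 to 6990 for those with time. Drug correlations lay between 0.915 and 0.946 at 16 h, 0.946 and 0.96 at 36 h, 0.949 and 0.962 with the inhibitor, 0.668 and 0.681 for digoxin at 16 h with ouabain at 36 h, and 0.679 and 0.709 for digoxin at 36 h with ouabain at 16 h. Replicate numbers did not pair libraries, as 198 pairs with the same number had a median r of -0.003 and 11 of 36 libraries were closest to their own number.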

Other observations

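The test of HRAS against other genes within groups, the residual and early against late tests of ouabain 16 h replicate 2, and the shared effect and single library tests of the inhibitor were set before their results. The camera tests of the fixed lists and the splits of the pairwise comparisons were planned, but what the splits would show was written down after the counts were seen. The remaining tests in this part were chosen after the result was seen.

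Some members of lists that were not called moved with digoxin. With digoxin and the inhibitor at 36 h, 4 of 16 unfolded protein response genes were higher and 7 lower (camera adjusted p = 0.823). Over all 18696 tested genes 5673 were higher and 5999 lower there. HERPUD1, which acts in the clearance of misfolded proteins, was at 2.24 ± 0.11 and SEL1L at -1.17 ± 0.07. In the same arm the chromatin protein HMGB2 rose 9.23-fold and the CDK inhibitor CDKN1C 37.5-fold. The MAP kinase feedback genes, which rose in senescence, had no common direction with digoxin at 16 h. There, 5 of 14 rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.582), with a median of -0.27 and a mean of 0.02. Over all tested genes 5285 of 18696 rose and 5859 fell.

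Zinc finger genes, a group chosen after the results were seen, fell at 16 h of treatment. Of 463 protein-coding genes named ZNF with a number, 306 fell and 51 rose with digoxin at 16 h, with a median log2 change of -0.9, and 282 fell and 49 rose with ouabain, with a median of -0.7. Of 10000 random lists matched in expression and length, medians lay between -0.56 and -0.2 with digoxin and between -0.46 and -0.16 with ouabain. At 36 h the medians were -0.06 and -0.08, above those of 99.89% and 97.92% of the matched lists, so the lower position did not last. A candidate explanation is that short-lived transcripts, such as those of many zinc finger genes, fall first, but no value here measures RNA stability.

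Replicate 2 of ouabain at 16 h lay between vehicle and the other ouabain libraries in all gene classes. Its median fraction of the full change was 0.59 and 0.56 in genes higher by 4-fold or more and by 2-fold to 4-fold, and 0.62 and 0.62 in lower genes, a spread of 0.06. A mixture with 0.61 of treated material left a median residual of 0.101, against 0.116 between replicates 1 and 3 (ratio 0.87), over the 2742 genes of these classes. The mixture was built from means of libraries with a fraction fitted to replicate 2, while replicates 1 and 3 are single libraries. A ratio under 1 thus does not show that the mixture fits as well as a replicate would. Some genes, chosen after their values were seen, do not follow the mixture. CXCL1 (42.6 CPM), CXCL3 (29.2) and CXCL5 (56.8) lay above both vehicle (17.5, 17.9 and 33.5) and the mean of the other ouabain libraries (30.9, 15.1 and 29.7), which no mixture of these gives. IL1B was only slightly higher, at 333 CPM against 299 and 311 CPM in those libraries. IL6, CXCL8, JUNB and FOS, chosen with them, lay between vehicle and the mean of those libraries. Early genes among the 2742 changed more with digoxin at 16 h than at 36 h, and late genes the reverse. Their fractions were close, 0.61 and 0.6 (a difference of 0 to 2 decimals, taken before rounding). This met the bound set beforehand against an earlier point of the time course. However, both classes had already changed 2-fold or more with digoxin at 16 h, and no library was taken before 16 h. The test thus cannot decide on an earlier point. The library may hold RNA mixed with untreated material, but that leaves CXCL1, CXCL3 and CXCL5 unexplained. Cells that did not respond, a weaker response in all cells or an earlier point of the time course cannot be separated from such a mixture.

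The inhibitor calls in vehicle-treated cells followed GC content, with rho of -0.39 in proliferating and -0.45 in senescent cells. After removal of GC and length trends 14% and 16.9% of the called genes stayed called, as the median absolute log2 change of the calls fell from 0.35 to 0.17 while the standard error stayed near 0.08. A trend of single libraries is argued against by slopes that spread by 0.024 within groups against a difference of -0.125 between the arms, a mean over the 4 treatments at 36 h (ratio 0.19). The trend is not confined to the inhibitor arm, as digoxin at 36 h without it had slopes of -0.087 to -0.113, and senescent vehicle cells with it -0.057 to -0.103. A shared part remained, since after correction the inhibitor changes of the proliferating and senescent arms, which share no library, correlated across genes with r = 0.222 (0.277 before). The arm of the inhibitor and a batch of libraries cannot be told apart because the labels give no batch.

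HRAS reads may come largely from the introduced ER:RAS construct. NRAS did not follow HRAS with digoxin at 16 h, its change being -0.19 of that of HRAS, which argues against a rise that NRAS shares at that time. At 36 h NRAS stood at 82.5 ± 10.9 CPM with digoxin and 69.5 ± 4.46 CPM with ouabain, against 69.6 ± 1.69 CPM in senescent vehicle cells. By bounds set beforehand, a correlation of ESR1 with HRAS within groups above that of 99% of other genes was to count for the construct and one under the 95% mark against it. It exceeded that of 90.1% of 10759 genes, so it met the bound against the construct. That bound took no account of deviations of whole libraries, since without the 2 deviating libraries the percentile was 99. Also, over the 12 groups ESR1 ranked 3 among these genes by the constancy of its ratio to HRAS, but both values, and the choice not to let the bound decide, came after that result was seen, so the source stays open.

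For each pairwise comparison, 6 libraries allow 10 splits, so the share of splits with as many genes cannot be under 0.1. The other splits mix libraries of both compared groups, so a difference between the groups itself widens the spread and lowers their counts. Low counts in those splits therefore do not test chance. The real split gave 6612, 10225 and 11157 genes for senescence at 16 h, 36 h and with the inhibitor, 11511, 12330 and 11685 for digoxin, 8750, 11915 and 11338 for ouabain, 2150 and 933 for ouabain against digoxin at 36 h and with the inhibitor, and 665, 5562 and 2786 for the inhibitor in proliferating, senescent vehicle and ouabain-treated cells, with 0 genes in the highest other split and 1 split as large, the real one. For the inhibitor with digoxin the real split gave 434 and the highest other 2. For ouabain against digoxin at 16 h the real split gave 0 genes, as did the other splits (10 of 10), with 2110 genes at an unadjusted p under 0.05, whereas fits of all 36 libraries called 923 with edgeR and 1218 with DESeq2.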
